A study of Homo sapiens with 8 samples.

How the data were processed

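The deposited table holds 1 value per probe set and array for 8 arrays of the Affymetrix human U133 2.0 type (A set), hybridised with cDNA labelled by the NuGEN Applause system from total RNA, per the labels' protocols. The values are intensities on a linear scale, and the authors used MAS5, per the submitters' processing notes, with no version given. The target level, the floor and any detection calls are not given in the sources used here. In the table itself the 2 to 98 percent trimmed means of the arrays differed by a factor of 1.00, no value lay below 50, and 41.2% of all values equalled 50, so the arrays had been scaled to a common level and floored before deposit. A level of 50 is therefore an upper bound, and a fold against it is a lower bound. Array scaling of this kind assumes that total signal is equal in all groups. No arrays held identical values.

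Samples were grouped by the labels into the 8 combinations of CHX, infection and IFN-γ, with 1 array each. Nothing says that the arrays came from separate days or cultures, so p-values measure only the spread between these arrays. The multiplicity of infection is not given in the sources used here. Of 22277 probe sets, 62 were controls and were left out. In the platform annotation 19070 named 1 gene, 1043 named several and 2164 are not listed with a gene in it. Of the 19070, 19058 matched a current gene record by identifier, 12 kept the name in the annotation, and no symbol changed. Each gene was represented by the probe set with the highest mean among those that name only it, which gave 11963 genes. Some genes are not analysed here. Coordinates are not printed, because no common genome build is named.

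Values were analysed as log2(intensity + 50), which understates the change of genes near the floor. The pseudocount had been set as the 20th percentile of all values and the filter as a value above the 40th percentile in at least 2 of the 8 arrays. Both percentiles equalled the floor of 50, so the filter keeps genes above the floor on 2 arrays, 7975 in all. Main effects were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as an additive model of the 3 factors with 4 residual degrees of freedom. Its residual holds both array noise and any interaction. Interactions were fitted in a model with all pairwise terms, whose only residual is the 3-way interaction with 1 degree of freedom. That model has no residual on 7 arrays, so for leaving out an array each interaction was fitted as the only one in the model. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. All adjusted p printed for single genes come from these limma fits. The 4 differences of a factor share no array. Differences within a single background compare 1 array with 1 array and carry no test.

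In all, 23 gene lists were fixed before the data were examined, and 114 combinations of list and effect with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over all 114. Of these 27 passed, none passed with an estimated correlation, and 5 passed with fry, which tests whether a list moves on balance to one side: the immediate early, NF-κB, heat shock, nonsense-mediated decay and histone lists under CHX. The version with an estimated correlation fitted each interaction as the only one in the model. Its higher p-values do not come from correlated genes alone. For the nonsense-mediated decay list under CHX the estimate was 0.011, but the camera p rose from 3.84e-05 to 0.0150. A list median within a background was set against 10000 random lists matched on size and mean level. To measure how much of the IFN-γ induction is kept in infected cells, genes were chosen by a log2 rise of at least 1 in uninfected cells of a given CHX state. They were measured on the arrays of the other CHX state, so that array noise in the choice could not lower the infected value. The choice can still favour genes that respond more in uninfected cells, and genes were not chosen in infected cells.

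Genes named in the text follow a rule set at the same stage. For each factor these are the 12 genes with the largest fitted change per direction among those past the threshold with the same sign in all 4 backgrounds. For each interaction they are the 8 largest past the threshold, and for the difference in cells free of the other 2 treatments the 10 largest rises. For a factor with fewer than 5 genes past the threshold, they are the 12 per direction with the largest smallest difference. Members of fixed lists may be named within the account of their list.

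The fits were tested on simulated data with 7975 genes, of which 200 changed, in 10 draws each. Of genes changed by 0.5 on the log2 scale, 76.0% were recovered for CHX, 76.1% for IFN-γ and 72.5% for infection. Of genes changed by 1, 98.4% or more were recovered for each of the 3, and 4.74% to 5.70% of the calls were false. For the interaction model, 52.1% of changes of 1 were recovered for infection with IFN-γ, 55.4% for CHX with IFN-γ and 54.0% for CHX with infection. Its false calls were 12.0%, 17.5% and 10.1% in the same order, above the nominal 5%. With each gene's own spread in place of a drawn spread, 88.8%, 83.7% and 86.6% were recovered and 18.1%, 14.9% and 14.7% of the calls were false. With nothing changed, the CHX with IFN-γ interaction gave calls in 3 of 10 draws with a drawn spread (at most 5 genes) and in 9 of 10 with the own spread (at most 45 genes). Infection with IFN-γ gave calls in 3 of 10 (at most 1 gene) and 7 of 10 (at most 30 genes), in the same order. For CHX with infection it was 0 of 10 and 5 of 10 (at most 16 genes). Interaction calls, that of *CXCL10* included, are therefore less reliable than their adjusted p. These simulations assume the same change in every background.

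Alternatives were pseudocounts of 0, 1 and 200, no filter and stricter filters, quantile normalization, median centring, the mean of all probe sets of a gene, preference for specific probe sets, variance shrinkage with trend and robust settings, other model terms, a lower choice threshold, other list tests, and leaving out each array in turn. The pseudocounts of 0 and 200, the filter above the floor on all 8 arrays and the doubt about the unstimulated CHX-free uninfected array were added after the data were seen.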

Results

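Gene expression was measured on 8 arrays of human foreskin fibroblasts, primary connective tissue cells in which the parasite *Toxoplasma gondii* is routinely grown. The 8 groups were all combinations of 3 factors, with 1 array per group. The factors were cycloheximide (CHX), infection with the type I strain RH 1-1, and interferon gamma (IFN-γ). CHX blocks protein synthesis at the ribosome, and the IFN-γ receptor signals through JAK kinases and STAT transcription factors. CHX was present at 50 µg/ml from 40 min before the parasites were added until harvest, 2 h 40 min in all. Infection preceded the IFN-γ step by 1 h, and IFN-γ was given at 100 U/ml for 1 h. The design asks which genes respond to IFN-γ within 1 h, whether infected cells respond alike, and which responses need no newly made protein. No group has a replicate array. Each effect of a factor is therefore the mean of 4 differences between arrays that share no array. The sign ± denotes the standard error of the fitted log2 effect (n = 4 arrays per level). Trimmed mean intensities ran from 505.5 to 506.0, values were floored at 50, and 7975 genes were tested. The number of arrays limits the precision of every value.

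IFN-γ raised 19 genes and lowered 1 within 1 h, taken over cells with and without infection and CHX. The largest rise was that of *CCL8*, a monocyte-attracting chemokine. It lay at the floor of 50 in all 4 unstimulated groups and reached 1149.5 in uninfected cells, 519 in infected cells, 833 in uninfected cells with CHX and 558 in infected cells with CHX. Those levels are at least 23.0-fold, 10.4-fold, 16.7-fold and 11.2-fold above the unstimulated arrays. The fitted log2 effect was 2.96 ± 0.16 (adjusted p = 1.22e-04). *IRF1*, the transcription factor that drives much of the later IFN-γ response, rose by 2.09 ± 0.15 (adjusted p = 4.59e-04), from 168 to 1424 in uninfected cells without CHX. The only gene that fell was *DDIT3*, the stress transcription factor CHOP, at -0.73 ± 0.10 (adjusted p = 0.0199), and it was lower after IFN-γ in all 4 backgrounds. That call was lost with the backgrounds as a block (adjusted p = 0.0599), with the mean of all probe sets (0.0628) and with a pseudocount of 200 (0.134), and without any of the 4 CHX arrays or the uninfected IFN-γ array, where for *DDIT3* the adjusted p ran from 0.0728 to 0.180.

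Other transcripts that rose with IFN-γ were *LRRTM2*, a leucine-rich repeat membrane protein (2.23 ± 0.28), the antiviral protein gene *IFIT3* (1.76 ± 0.18), the Wnt receptor *FZD5* (1.60 ± 0.10), the adhesion molecule *ICAM1* (1.41 ± 0.22) and the GTPase *GBP1* (1.35 ± 0.14). *PLSCR1* (1.24 ± 0.20), *ZNF267* (1.13 ± 0.10), *RGS16* (1.12 ± 0.16), *APOL6* (1.11 ± 0.14) and *OAS1* (1.05 ± 0.12) followed. Their adjusted p ran from 2.55e-04 for *FZD5* to 0.0488 for *ICAM1* and *PLSCR1*. Each was higher after IFN-γ in all 4 backgrounds, as the rule for naming genes required. Of the 7975 genes, 12 had differences of at least 1.5-fold in all 4 backgrounds. Of these 11 were higher in each and 1 was mixed, whereas random signs would give the same direction in 12.5%.

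**Figure D1:**
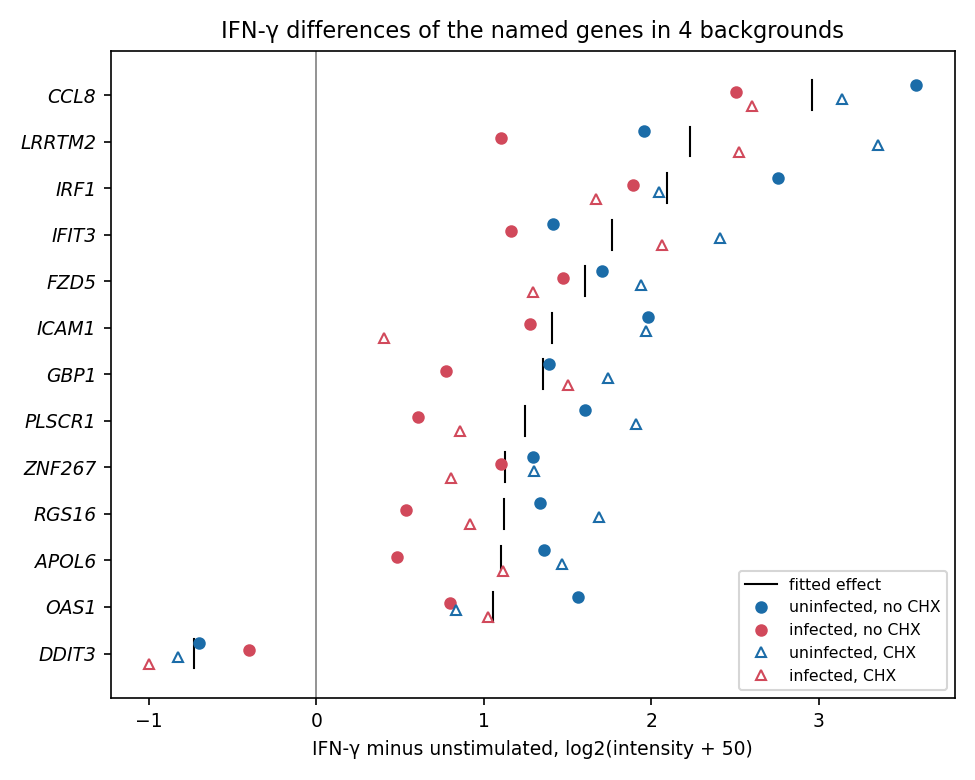
Difference between the IFN-γ-stimulated and the unstimulated array on the log2(intensity + 50) scale (x axis) for the 12 genes with the largest fitted rises and the only gene that fell (y axis), in each of 4 backgrounds; each symbol is 1 array minus 1 array, blue for uninfected and red for infected cells, filled circles without CHX and open triangles with CHX, and black lines mark the fitted effect. Every symbol of the 12 raised genes lies above 0, with *CCL8* highest at a fitted 2.96, and all 4 symbols of *DDIT3* lie below 0. The rule that chose these genes required the same sign in all 4 backgrounds.

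Among the 38 measured members of the early IFN-γ response list, 6 rose, namely *CCL8*, *IRF1*, *GBP1*, *ICAM1*, *APOL6* and the peptide transporter *TAP1* (0.71 ± 0.08, adjusted p = 0.00625). The other 32 did not pass the test. Adjusted over the list alone, 14 rose and 1 fell. The added members included *SOCS1* (0.62 ± 0.15), an inhibitor of JAK kinases, and *PSMB8* (0.53 ± 0.11), a subunit of the immunoproteasome. The list as a whole moved up (camera adjusted p = 7.99e-15; adjusted p = 0.328 with an estimated correlation). Of 29 interferon-stimulated genes best known from the type I response, 3 rose (*IFIT3*, *OAS1* and the RNA sensor *IFIH1* at 0.66 ± 0.08), and 11 rose adjusted over the list alone, among them *ISG15* (0.84 ± 0.17). That list moved up too (camera adjusted p = 3.14e-10; adjusted p = 0.330 with an estimated correlation). None of 15 antigen presentation genes and late effectors passed the test over all genes. Of them 2 did adjusted over the list alone (*HLA-E* at 0.30 ± 0.08 and *HLA-G* at 0.45 ± 0.13). The list did not pass (camera adjusted p = 0.131), with 12 of 15 members positive.

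For 5 other lists the preset-correlation test gave a lower level after IFN-γ, most clearly in uninfected cells with CHX. The 27 genes of ER stress and the amino acid response held 1 member that fell, *DDIT3*, and 2 adjusted over the list alone, the other being *DDIT4* (-0.77 ± 0.19; camera adjusted p = 5.82e-04, adjusted p = 0.330 with an estimated correlation). No member passed the test among the 16 immediate targets of TGF-β and BMP (camera adjusted p = 0.00238), the 27 fibroblast matrix and contractile genes (0.00694), the 20 cholesterol genes (0.0455) and the 47 cytosolic ribosomal proteins (3.31e-05). With an estimated correlation the adjusted p of these 4 lists was 0.531, 0.672, 0.672 and 0.815, in the same order. Against matched random lists their medians lay at percentiles of 0, 7.67, 0.05 and 1.67 in uninfected cells with CHX, but at 30.6, 48.3, 62.7 and 43.2 in infected cells without CHX. The IFN-γ difference of the 47 ribosomal proteins was higher in infected than in uninfected cells, by a median of 0.09 without CHX and 0.17 with CHX. Adjusted over the list alone, *ID1*, an inhibitor of DNA-binding proteins, fell by 0.54 on the log2 scale. Without a filter on low values none of the 20 genes passed the test. The count was 12 without the uninfected IFN-γ array, 11 without the uninfected CHX array, 9 without the uninfected CHX and IFN-γ array, 10 without the infected CHX array and 12 without the infected CHX and IFN-γ array. The count was 11 with the mean of all probe sets per gene and 12 with the 4 backgrounds as a block. The calls of *ICAM1* and *PLSCR1* were lost under most of the alternatives, those of *APOL6* and *RGS16* with the block, and those of *LRRTM2*, *OAS1*, *APOL6* and *RGS16* with the mean of all probe sets.

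The next comparison was that of the IFN-γ response between infected and uninfected cells. *SOCS3*, a feedback inhibitor of JAK signalling, went from the floor of 50 to 469 with IFN-γ in uninfected cells and from 174 to 286 in infected cells, and with CHX from 205 to 953 and from 687 to 926. The interaction of infection and IFN-γ, which is the IFN-γ difference in infected cells minus that in uninfected cells, was -1.68 ± 0.16 for *SOCS3* (adjusted p = 0.236) and -1.66 ± 0.18 for *CISH*, a related inhibitor of cytokine signalling (adjusted p = 0.236). The chemokine gene *CCL2* went from 437 to 3469 with IFN-γ in uninfected cells and from 2269.8 to 2618 in infected cells, and with CHX from 1853 to 3183 and from 2582 to 3591. Its fitted IFN-γ effect was 1.07 ± 0.36 (adjusted p = 0.552), and 0.55 without the unstimulated CHX-free uninfected array, to which the 437 belongs. *CCL8* reached 519 in infected cells against 1149.5 in uninfected cells, and 558 against 833 with CHX. No gene passed the test of this interaction with limma over all genes, while 427 had an unadjusted p under 0.05 where chance gives 399.

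As a group, the early IFN-γ response list had a smaller response in infected cells. The median interaction of its 38 members was -0.21, and 8 members were positive. Adjusted over the list alone 5 fell (*SOCS3*, *ICAM1*, *PIM1*, *CCL8* and *CEBPD*; camera adjusted p = 1.94e-06, adjusted p = 0.328 with an estimated correlation). The 29 type I interferon-stimulated genes had a median interaction of -0.23 with 6 positive and no member passing (camera adjusted p = 8.26e-04, adjusted p = 0.647 with an estimated correlation). The 24 JAK-STAT components had a median of -0.13 (camera adjusted p = 0.00661, adjusted p = 0.661 with an estimated correlation). Their 2 members that fell adjusted over the list alone were *SOCS3* and *CISH*. On the CHX arrays alone, which leave out the unstimulated CHX-free uninfected array, the median was -0.20 for the early response list, -0.05 for the type I list and -0.05 for the JAK-STAT list, with SDs of random lists of 0.05, 0.05 and 0.06. Positive medians were found for the 49 immediate early genes (0.15, camera adjusted p = 0.0411) and the 47 ribosomal proteins (0.13, camera adjusted p = 4.00e-04), both with an adjusted p of 0.815 with an estimated correlation and no member passing. The median IFN-γ difference of the early response list was 0.25 in uninfected and 0.15 in infected cells, and 0.45 and 0.13 with CHX. The 4 medians lay at the 99.1 percentile or higher among the medians of 10000 random lists of the same size and mean level. For the type I list the medians were 0.50 and 0.08, and with CHX 0.28 and 0.19.

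The induction was also measured on genes chosen on other arrays, all of uninfected cells, a choice that can favour genes with a larger response there. The 44 genes with an IFN-γ rise of at least 2-fold in uninfected cells without CHX had, on the CHX arrays, a median log2 difference of 0.72 in uninfected cells and 0.39 in infected cells, or 53.6%, and 38 of the 44 were smaller in infected cells. The 27 genes chosen in uninfected cells with CHX had, on the arrays without CHX, medians of 1.103 and 0.5507, or 49.9%, with 22 of the 27 smaller. The SD of medians of matched random lists was 0.04 and 0.06. With genes chosen at a log2 difference of 0.58, the medians were 0.08 and 0.08 for genes chosen without CHX and 0.25 and 0.23 for genes chosen with CHX, so the difference was not seen. Genes chosen without CHX at 0.58 had almost no induction in uninfected cells, so their medians cannot show whether the difference is absent. Under median centring 17 genes passed the interaction test, under robust variance shrinkage 11, and with quantile normalization 2, against 0 as fitted. Simulated data with nothing changed and each gene's own spread gave up to 30 calls for this interaction, so such counts are no sign of a real difference. With this interaction as the only one in the model the count was 0 on all 8 arrays and 4 without the uninfected CHX array. The unstimulated CHX-free uninfected array, from which 1 of the 4 IFN-γ differences is taken, had an *ACTB* 3' to 5' control ratio of 13.9 against 6.94 to 10.2 on the other 7 arrays.

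**Figure D2:**
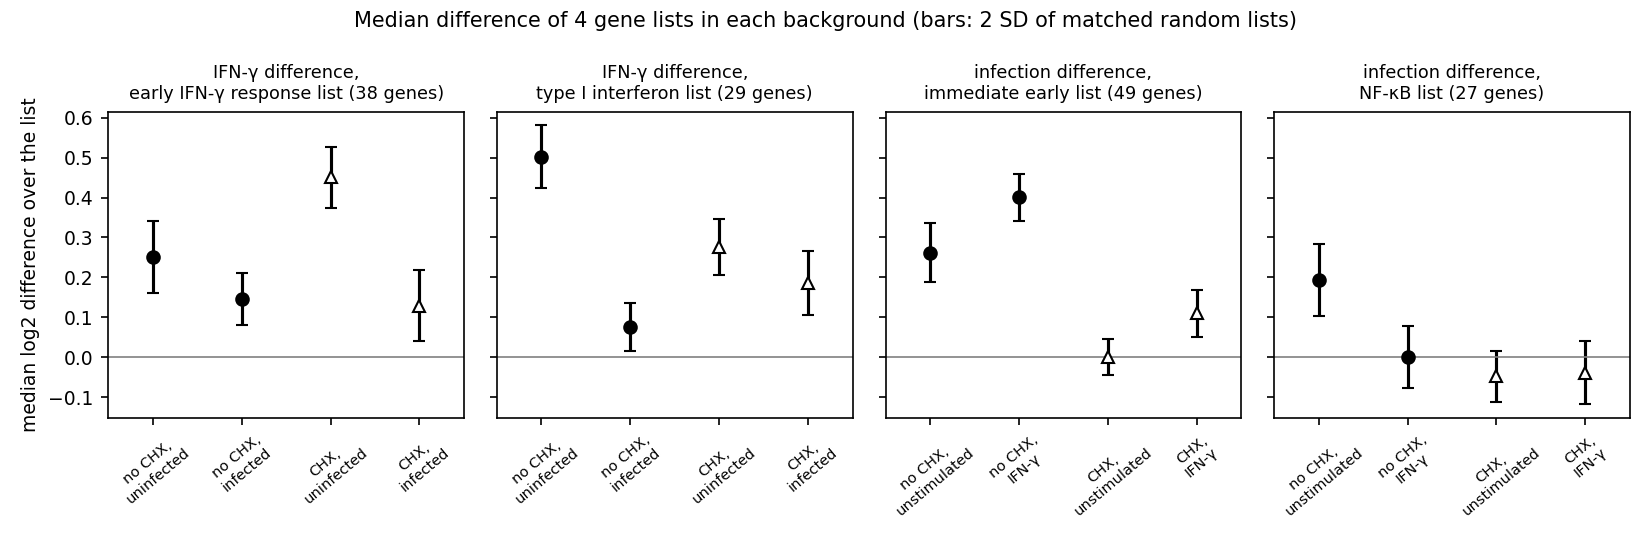
Median log2 difference over the genes of a list (y axis) in each of 4 backgrounds (x axis), for the IFN-γ difference in the early IFN-γ response list and the type I interferon list and for the infection difference in the immediate early and NF-κB lists; filled circles are without CHX, open triangles with CHX, and bars are 2 SD of the medians of matched random lists, not a replicate error. The early response list lies at 0.25 and 0.15 without CHX and at 0.45 and 0.13 with CHX in uninfected and infected cells.

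All 19 genes raised by IFN-γ were higher after it in all 4 backgrounds, those with CHX included. The additive test favours such agreement, and the rule for the 12 genes named above required it, so this is no separate test. The induction of *CXCL10*, a T cell chemokine, was far larger with CHX than without. *CXCL10* was at the floor of 50 on all 4 unstimulated arrays. With IFN-γ it reached 119 in uninfected and 82.0 in infected cells without CHX, and 1653 and 1164 with CHX, at least 33.1-fold and 23.3-fold over the unstimulated arrays. Its interaction of CHX and IFN-γ, the IFN-γ difference with CHX minus that without, was 3.27 ± 0.16 (adjusted p = 0.00457). It was the only gene to pass, while 441 genes had an unadjusted p under 0.05. *IRF1* reached 2454 with CHX and IFN-γ and 1424 with IFN-γ alone, from 556 and 168. The early response list did not pass the test of this interaction (median interaction -0.07, 1 of 38 members passing, camera adjusted p = 0.959). Adjusted over the list alone, the IFN-γ response of *IFIT3* (0.95 ± 0.16) and *ISG15* (0.88 ± 0.17) was larger with CHX among the type I genes. The 49 immediate early genes had a median interaction of -0.11, with *DUSP2* and *EGR4* lower adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.815 with an estimated correlation). In a model with this interaction alone the count was 1 on all 8 arrays and 0 without the uninfected CHX and IFN-γ array. The *CXCL10* call was also lost with either stricter filter or none, while median centring gave 21 genes and robust variance shrinkage 13.

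**Figure D3:**
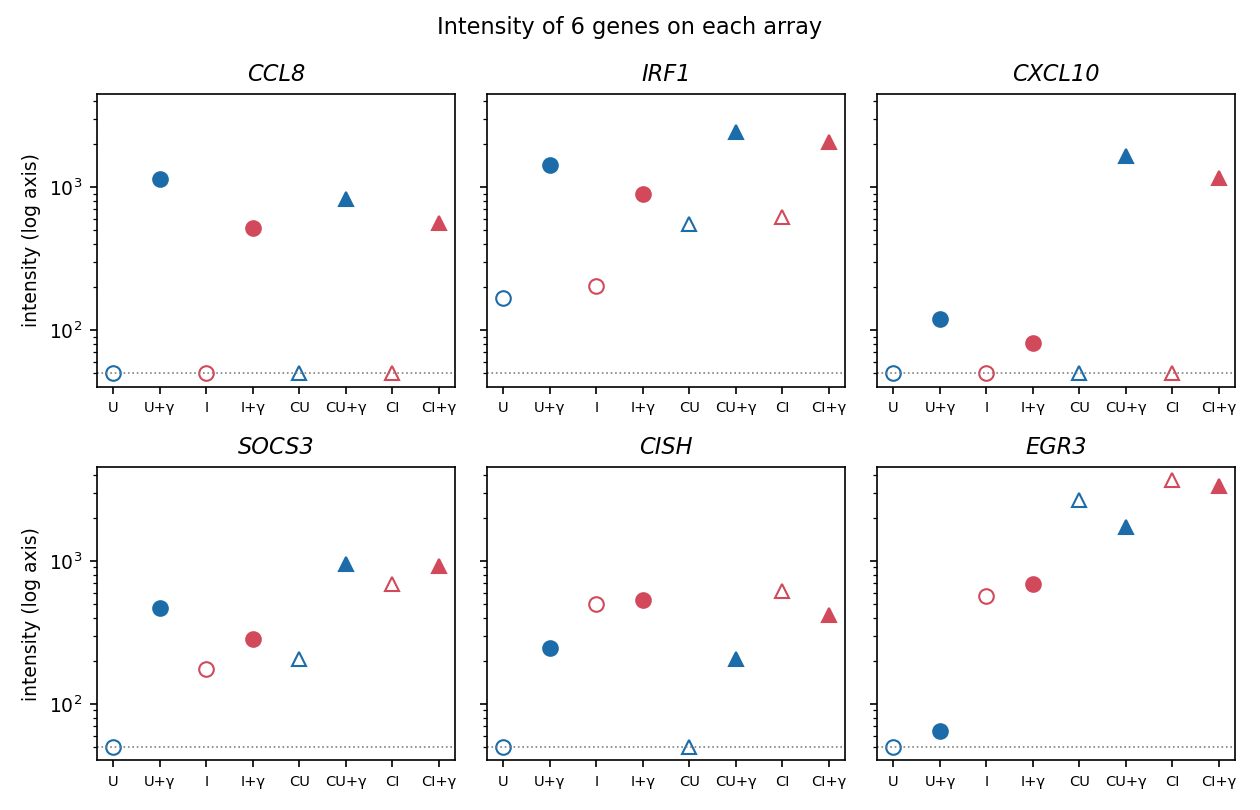
Intensity on a log axis (y) of 6 genes on each of the 8 arrays (x: U uninfected, I infected, C with CHX, γ with IFN-γ); each symbol is 1 array, blue for uninfected, red for infected, triangles with CHX, open symbols unstimulated, and the dotted line is the floor of 50. *CXCL10* is at 119 and 82.0 with IFN-γ alone and at 1653 and 1164 with CHX and IFN-γ, and *CISH* is at 502 in infected unstimulated cells and at 50 in uninfected unstimulated cells.

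Infection for 2 h was compared with no infection to ask what the parasite itself does to host transcripts. *CISH* lay at the floor of 50 in uninfected unstimulated cells and at 502 in infected cells without CHX and 614 with CHX, the latter at least 12.3-fold higher than without infection. Its fitted log2 effect was 1.77 ± 0.29 (adjusted p = 0.173). *FOLR1*, a folate receptor, was higher in all 4 backgrounds by 4.08-fold, 2.20-fold, 2.48-fold and 2.59-fold, with a fitted effect of 1.02 ± 0.11 that missed the threshold (adjusted p = 0.0526). *FOLR1* passed with the backgrounds as a block (adjusted p = 0.0472), all pairwise terms (0.0235), trend and robust shrinkage (0.00606), median centring (0.00701) and either stricter filter (0.0359 and 0.0269), and in 3 of 8 fits that leave out an array. In the others the adjusted p of *FOLR1* reached 0.472, without the infected CHX array. The transcription factor *EGR3* was at 50 without and 570.3 with infection in CHX-free unstimulated cells and at 2646 and 3654 with CHX. Its effect was 1.68 ± 0.35 (adjusted p = 0.272). No gene passed the test for infection with limma, and 618 had an unadjusted p under 0.05 where chance gives 399. The genes named here were therefore taken by the size of their smallest difference over the 4 backgrounds and are given as values.

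Other genes higher in infected cells in all 4 backgrounds were the nuclear receptors *NR4A2* (1.26 ± 0.19) and *NR4A3* (1.18 ± 0.25), *CEBPD* (1.16 ± 0.22), the phosphatase *DUSP2* (0.99 ± 0.21), the proto-oncogene *MYB* (0.88 ± 0.15), *KLF2* (0.59 ± 0.08), the purine enzyme *PNP* (0.50 ± 0.08), *TECPR2* (0.47 ± 0.08) and *ZNF324* (0.42 ± 0.08). Genes lower in all 4 were *HNRNPL* (-0.64 ± 0.14), the interferon-inducible *PARP12* (-0.59 ± 0.10), *DUSP10* (-0.56 ± 0.14), the Wnt regulator *DACT1* (-0.56 ± 0.10), *AKIRIN2* (-0.53 ± 0.10), the receptor kinase *EPHA2* (-0.52 ± 0.09), *DDIT3* (-0.51 ± 0.10), *SIVA1* (-0.45 ± 0.08), the RNA-binding protein gene *ELAVL1* (-0.42 ± 0.07), *NFATC4* (-0.41 ± 0.07), *HIP1R* (-0.37 ± 0.07) and the zinc transporter *SLC30A1* (-0.36 ± 0.09). Among the largest rises in unstimulated CHX-free cells were also *PDE4B*, a cAMP phosphodiesterase, at 877 against 198, *VEGFA* at 1113 against 304 and *IL6* at 466 against 104. The lower value of each is from the unstimulated CHX-free uninfected array, which stood apart in several of its controls. Without that array the fitted infection effect was 0.40 for *VEGFA*, 0.70 for *IL6* and 0.89 for *PDE4B*.

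Immediate early genes, the transcription factors and regulators switched on within minutes of a stimulus, lay higher in infected cells as a group. Of 49, 39 had a positive fitted effect, with a median of 0.24. None passed over all genes and 9 rose adjusted over the list alone, including *KLF2*, *NR4A2*, *FOSB* and *HBEGF* (camera adjusted p = 1.68e-12, adjusted p = 0.441 with an estimated correlation). The 27 NF-κB targets had a median of 0.09 (camera adjusted p = 0.0406, adjusted p = 0.815 with an estimated correlation) and no member passed. Their median was 0.19 in unstimulated cells without CHX, against the array that stood apart, and 0.00, -0.05 and -0.04 in the other 3 backgrounds. All 7 histone genes had a negative fitted effect, with a median of -0.21 and no member passing (camera adjusted p = 0.00311, adjusted p = 0.661 with an estimated correlation). Their median infection difference was 0.04 in unstimulated and -0.11 in IFN-γ-stimulated cells without CHX, and -0.55 and -0.23 with CHX. The infection count was 1 without the unstimulated CHX-free uninfected array, 1 without the uninfected IFN-γ array and 5 without the infected CHX and IFN-γ array. A model with all pairwise interactions gave 11 genes, all higher, among them *CISH* (adjusted p = 0.00372).

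On the log2 scale, the infection difference of the immediate early genes was smaller with CHX than without. The median infection difference of the 49 genes was 0.26 in unstimulated and 0.40 in IFN-γ-stimulated cells without CHX, and 0.00 and 0.11 with CHX. The median interaction of CHX and infection was -0.23, and 12 members fell and 3 rose adjusted over the list alone (camera adjusted p = 4.12e-09, adjusted p = 0.424 with an estimated correlation). *EGR3* (-1.97 ± 0.18), the kinase-related *TRIB1* (-1.22 ± 0.16) and *HBEGF* (-1.22 ± 0.22) were negative. *EGR4* was positive (2.08 ± 0.17), at 50 in all CHX-free groups, at 687 in uninfected and 2694 in infected cells with CHX. The NF-κB list had a median interaction of -0.28, with *CXCL1*, *IL6*, *CXCL8* and *IL11* among 6 that fell adjusted over the list alone (camera adjusted p = 7.33e-09, adjusted p = 0.328 with an estimated correlation). The 16 EGFR ligands and feedback genes had a median of -0.16, with *HBEGF* and *VEGFA* (-1.03) lower adjusted over the list alone (camera adjusted p = 0.00349, adjusted p = 0.531 with an estimated correlation). All 7 histone genes were negative (median -0.31, camera adjusted p = 8.96e-04, adjusted p = 0.569 with an estimated correlation), and 46 of 47 ribosomal proteins were positive (median 0.18, camera adjusted p = 3.14e-10, adjusted p = 0.672 with an estimated correlation), with no member passing in either list. In IFN-γ-stimulated cells, which leave out the array that stood apart, the median was -0.25 for the NF-κB list, -0.06 for the EGFR list and -0.07 for the histone genes, with SDs of random lists of 0.06, 0.07 and 0.11. No gene passed this interaction over all genes with limma, and 315 had an unadjusted p under 0.05 where chance gives 399. Median centring gave 27 genes, robust variance shrinkage 37 and quantile normalization 10.

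CHX had the largest effect of the 3 factors, with 509 genes raised and 355 lowered. The immediate early genes *FOSB* (4.33 ± 0.19), *FOS* (3.76 ± 0.11), *ATF3* (3.48 ± 0.27), *EGR3* (3.37 ± 0.35), *EGR4* (3.36 ± 0.38) and *DUSP1* (2.70 ± 0.18) rose most, along with the inflammatory genes *CXCL8* (3.91 ± 0.21), *PTGS2* (3.19 ± 0.22), *CXCL2* (3.18 ± 0.14), *IL6* (3.03 ± 0.25) and *TNFAIP3* (2.89 ± 0.12) and the vasoconstrictor *EDN1* (2.76 ± 0.16). *FOS* was at the floor of 50 in uninfected cells and at 1061 with CHX, at least 21.2-fold higher. The adjusted p of these 12 ran from 2.79e-07 for *FOS* to 6.77e-04 for *EGR4*. Rises of at least 2-fold were found for 90 genes and falls of that size for 2, *TRIB2* (-1.21 ± 0.10) and *GTF2H2B* (-1.02 ± 0.11). Falls followed for *RASL11B* (-0.96 ± 0.20), *ATP2C2* (-0.89 ± 0.14), the ubiquitin ligase adaptor *KBTBD11* (-0.83 ± 0.15), the homeobox gene *MSX1* (-0.83 ± 0.10), *CBR3* (-0.82 ± 0.17), *ZNF174* (-0.79 ± 0.13), the receptor kinase *KIT* (-0.78 ± 0.11), *AOPEP* (-0.76 ± 0.08), *TBCC* (-0.74 ± 0.09) and the ganglioside enzyme *ST3GAL5* (-0.69 ± 0.07).

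By list, 41 of 49 immediate early genes rose with CHX and none fell, and their median effect was 1.25 (camera adjusted p = 3.61e-44, adjusted p = 0.328 with an estimated correlation). Of 27 NF-κB targets 16 rose, among them *NFKBIA* (1.86 ± 0.08), the inhibitor that NF-κB itself induces (camera adjusted p = 9.23e-19, adjusted p = 0.328 with an estimated correlation). All 7 histone genes rose, led by *H2BC21* (2.04 ± 0.10; camera adjusted p = 2.20e-11, adjusted p = 0.330 with an estimated correlation). Of 16 EGFR ligands and growth factor feedback genes 6 rose, including *HBEGF* (2.15 ± 0.23) and *EREG* (1.11 ± 0.19; camera adjusted p = 1.63e-05, adjusted p = 0.374 with an estimated correlation). Of 23 transcripts known to be degraded by nonsense-mediated decay, a pathway that needs translation, 5 rose, among them *CCNL1* (1.98 ± 0.10) and *SAT1* (1.53 ± 0.08; camera adjusted p = 3.37e-04, adjusted p = 0.328 with an estimated correlation). Of 15 heat shock genes 3 rose, led by *DNAJB4* (0.80 ± 0.09; camera adjusted p = 0.00751, adjusted p = 0.330 with an estimated correlation).

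Among the 38 early IFN-γ response genes, CHX raised 5, *ICAM1* (1.78 ± 0.22), *SOCS3* (1.39 ± 0.30), *IRF1* (1.20 ± 0.15), *BCL6* (1.08 ± 0.10) and the kinase *PIM1* (0.91 ± 0.14), and lowered *APOL3* (-0.46 ± 0.08). The list did not pass (camera adjusted p = 0.237). The ER stress list held 4 genes that rose, led by *DDIT3* (1.92 ± 0.10), and 4 that fell, among them the serine synthesis enzyme *PHGDH* (-0.41 ± 0.09). Of 18 p53 targets 4 rose, led by the cytokine *GDF15* (1.51 ± 0.11), and the list did not pass (camera adjusted p = 0.0858). None of the 27 fibroblast matrix and contractile genes and none of the 47 ribosomal protein genes passed. The CHX count was 491, 519, 556 and 574 without, in turn, the uninfected CHX array, the infected CHX-free array, the infected IFN-γ array and the infected CHX array, and 240 without a filter on low values. Without the filter *EGR3*, *EGR4*, *RASL11B*, *ATP2C2*, *KBTBD11*, *MSX1*, *CBR3*, *ZNF174* and *KIT* lost their calls. Of the 8 fits that leave out an array, *RASL11B* passed in 4, with an adjusted p of up to 0.0595, and *CBR3* in 5, with up to 0.0536. The number lowered was 235 in a model with all pairwise interactions.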

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

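The tests below of the array with low control values, of a higher level before IFN-γ and of a ceiling were chosen after the result was seen, and the other tests here were set before their results were seen. Each list or gene value in the next paragraph was picked out because an effect differed between groups by a test of the difference itself, using the preset-correlation list test or limma for single genes. The counts of probe sets that name no single gene were picked out as data outside the analysed genes, from tests of main effects. None of the lists passed with an estimated correlation, and the interaction fit has 1 residual degree of freedom.

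For infection and IFN-γ the medians of the differences of log2 differences were -0.206 for the early IFN-γ response list, -0.2292 for the type I interferon-stimulated genes, -0.1293 for the JAK-STAT components, 0.1544 for the immediate early genes and 0.126 for the ribosomal proteins. For CHX and IFN-γ they were 3.266 for *CXCL10* and -0.1071 for the immediate early genes. For CHX and infection they were -0.2332 for the immediate early genes, -0.2804 for the NF-κB targets, -0.1573 for the EGFR ligands and feedback genes, 0.1755 for the ribosomal proteins and -0.3076 for the histone genes. A further signal lay in probe sets outside the analysed genes, those that name no single gene. Of 3151 such probe sets 1517 were tested, and limma called 3 for infection, all higher, 215 for CHX, of which 126 were higher and 89 lower, and 0 for IFN-γ.

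The smaller IFN-γ response of infected cells was weighed against 3 technical explanations. For the early IFN-γ response list, an effect of the unstimulated CHX-free uninfected array alone is argued against by the CHX arrays. There the list had a median difference of differences of -0.1967 (SD of random lists 0.05, 29 of 38 negative). Genes chosen at 2-fold kept 53.55% of their IFN-γ difference on these arrays. Genes chosen at 0.58 had medians of 0.0763 in uninfected and 0.0758 in infected cells, too small an induction to show a loss. For the type I and JAK-STAT lists an effect of that array stays open. Their medians on the CHX arrays were -0.048 and -0.054 (SD of random lists 0.049 and 0.063), against -0.28 and -0.15 without CHX. A higher level before IFN-γ as the whole cause is argued against by the lower level after it, a median infected minus uninfected difference of -0.1447 on the CHX arrays and -0.36 on the others. Compression of falls on the arrays of infected cells is argued against by genes that CHX lowers. Their median change was a small -0.18 and -0.16 in uninfected cells and -0.29 and -0.29 in infected cells, or 167% and 185%. These falls do not test a compression of rises. Genes that CHX raises kept 79.2% of their change in infected cells when measured in unstimulated cells, and 91.2% when measured in IFN-γ-stimulated cells. Only the 79.2% was measured with the unstimulated CHX-free uninfected array. The genes that CHX raises most include immediate early and NF-κB genes, whose infection difference was smaller with CHX, so this shortfall is not separate evidence. A partial compression of rises may contribute, and whether the difference is biological stays undecided.

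The smaller infection response of immediate early genes with CHX, a difference on the log2 scale, was weighed against 2 technical explanations. CHX itself raised these genes in uninfected cells, by a median log2 difference of 1.52 unstimulated and 1.15 with IFN-γ. Whether this higher starting level accounts for the smaller log2 difference was not tested. A ceiling of the array signal is argued against by the 18 members under an intensity of 2000 on both uninfected CHX arrays, with a median interaction of -0.1768 (SD of random lists 0.06) and 13 negative. On the infected CHX arrays these reached at most 2694, where the highest value of a gene on any array was 9801.5. The unstimulated CHX-free uninfected array is argued against by the IFN-γ-stimulated cells, where it takes no part and the infection difference was smaller with CHX by a median of -0.2057. Members did not all go this way, since *EGR4*, *DUSP2* and *NR4A1* were positive adjusted over the list alone, and no biological explanation was tested.

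The 8 arrays can be split into 4 and 4 in 35 ways, of which 33 could be fitted with the other 2 factors in the model. For IFN-γ, 1 split, the real one, gave at least the 20 genes called, and the highest other count was 0. For CHX, 1 split, the real one, gave at least the 864 genes, with 0 as the highest other count. For infection the real count was 0 with limma (618 genes at an unadjusted p under 0.05), a count met by all 33 splits, and the highest other count was 1. When the other 2 factors act, only the 8 splits that take 1 array of each background can stand for chance, too few for a share under 0.05. In the other splits the factor itself is not in the model. Its effect then adds to the residual and lowers their counts, so the counts of 0 are no measure of chance.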

How the results depend on the processing

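The pseudocounts of 0 and 200 and the filter above the floor on all 8 arrays were chosen after the data were seen; the other alternatives were planned. Leaving out an array leaves its group empty. Main effects then come from the additive model and each interaction from a model with it alone, which on 8 arrays gave 0 for infection by IFN-γ, 1 for CHX by IFN-γ and 0 for CHX by infection. A floor of 50 under 41.2% of values limits every low gene. The 40th percentile as pseudocount equals the 50 in use and tests nothing. Of the results under the alternatives 1209 kept direction and side of the threshold or moved little, 122 moved, 55 no longer passed, 21 newly passed and 0 reversed. This tally includes the 40th percentile pseudocount. For the fits that leave out an array it holds gene counts only, so single genes that lost their calls there are not among the 55. Below, kept induction is the median IFN-γ difference of the chosen genes, and early list is the median of the early IFN-γ response list. As reported, the changed genes were 864 for CHX (509 higher, 355 lower), 20 for IFN-γ (19 and 1) and 0 for infection, and 0 for infection by IFN-γ, 1 for CHX by IFN-γ and 0 for CHX by infection, with 27 list calls. Kept induction was 0.7245 uninfected and 0.388 infected for genes chosen without CHX, and 1.103 and 0.5507 for genes chosen with CHX. The early list was at 0.2523 uninfected, 0.1461 infected, 0.4512 uninfected with CHX and 0.1297 infected with CHX. In what follows the cause was not tested.

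No filter: CHX by IFN-γ 0, CHX 240 (171 higher, 69 lower), IFN-γ 0 (0 higher, 0 lower, and 670 at an unadjusted p under 0.05 with limma), early list 0.2725 uninfected with CHX and 0.0818 infected with CHX. Filter above the median in 4 arrays: CHX by IFN-γ 0, as it removes *CXCL10*, infection 1 (1 higher), kept induction uninfected 0.672 (chosen without CHX) and 1.295 (with CHX), early list 0.3277 uninfected, 0.2414 infected and 0.1804 infected with CHX. Above the floor on all 8 arrays: CHX by IFN-γ 0, as it removes *CXCL10*, infection 1 (1 higher), kept induction 0.5255 uninfected and 0.3007 infected (without CHX) and 0.8126 uninfected (with CHX), early list 0.2316 uninfected with CHX and 0.0801 infected with CHX. Pseudocount 0: kept induction 0.4274 uninfected and 0.2841 infected (without CHX) and 0.6605 infected (with CHX), early list 0.3032 uninfected and 0.5092 uninfected with CHX. Pseudocount 1: kept induction 0.4227 and 0.283 (without CHX) and 1.168 and 0.6608 (with CHX), early list 0.302 uninfected and 0.5085 uninfected with CHX. Pseudocount 200: CHX by infection 1, IFN-γ 10 (10 higher, 0 lower), kept induction uninfected 0.5712 (without CHX), early list 0.1769 uninfected and 0.2593 uninfected with CHX.

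Quantile normalization: CHX by IFN-γ 2, CHX by infection 10, infection by IFN-γ 2, kept induction uninfected 0.7788 (without CHX) and 1.296 (with CHX), early list 0.1966 uninfected and 0.4097 uninfected with CHX. Median centring: CHX by IFN-γ 21, CHX by infection 27, infection by IFN-γ 17, infection 5 (5 higher), kept induction uninfected 1.286 (with CHX), early list 0.1808 uninfected and 0.3782 uninfected with CHX. Mean of all probe sets: IFN-γ 11 (11 higher, 0 lower), kept induction 0.838 uninfected and 0.3486 infected (without CHX), early list 0.3594 uninfected and 0.1837 infected with CHX. Specific probe sets preferred: early list 0.187 infected and 0.1835 infected with CHX. Variance shrinkage with trend and robust settings: CHX by IFN-γ 13, CHX by infection 37, infection by IFN-γ 11, infection 1 (1 higher). All pairwise interactions: CHX lower 235, infection 11 (11 higher). Backgrounds as a block, which pairs the 2 arrays of each background: IFN-γ 12 (12 higher, 0 lower), infection 1 (1 higher). Choice at 0.58: kept induction 0.0763 and 0.0758 (without CHX), 0.2461 and 0.2347 (with CHX). List calls were 0 with an estimated correlation and 5 with fry.

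Without each array in turn the counts ran from 491 to 987 for CHX (350 to 530 higher, 138 to 457 lower), 9 to 23 for IFN-γ (9 to 21 higher, 0 to 2 lower), 0 to 5 for infection (0 to 4 higher, 0 to 1 lower), 0 to 1 for CHX by IFN-γ and 0 to 4 for infection by IFN-γ. *CCL8*, *IRF1*, *FZD5*, *GBP1*, *IFIT3* and *ZNF267* passed whichever of the 8 arrays was left out, *OAS1* in 7 of 8, *LRRTM2* in 4, *DDIT3* in 3, *APOL6*, *ICAM1* and *RGS16* in 2 and *PLSCR1* in 1.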

Other observations

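The list tests in this part were planned, the counts without the array that stood apart were added after the data were seen, and the genes of the next paragraph were chosen after their values were seen.

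*EGR4*, a zinc-finger transcription factor, was at the floor of 50 on all 4 arrays without CHX. With CHX it was at 687 in uninfected and 2694 in infected unstimulated cells, and at 289.6 in uninfected and 1578 in infected cells with IFN-γ. *FOS* with CHX was at 1061 in uninfected and 1310 in infected unstimulated cells. *ZFP36*, whose protein destabilises cytokine transcripts, went from 210 to 982 with IFN-γ in uninfected cells without CHX, from 736 to 809 in infected cells, and stood at 2663 or above in all CHX groups. Its fitted IFN-γ effect was 0.59, and 0.16 without the unstimulated CHX-free uninfected array, to which the 210 of *ZFP36* belongs.

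Several lists did not pass the preset-correlation test for CHX. Of 27 glycolysis and hypoxia genes 5 rose, among them the glucose transporter *SLC2A3* (0.98), (camera adjusted p = 0.129). Of 20 cholesterol genes 3 rose, *HMGCS1* (0.60), *IDI1* (0.46) and *INSIG1* (0.46; camera adjusted p = 0.173). Of the 16 TGF-β and BMP targets 3 rose, *ID3* (0.60), *SMAD7* (0.45) and *ID4* (0.66), and *SMAD6* fell by 0.31 (camera adjusted p = 0.127). The median CHX difference of that list was 0.39 in unstimulated and 0.09 in IFN-γ-stimulated uninfected cells, and 0.12 and 0.05 in infected cells, at the 100, 96.7, 98.9 and 86.9 percentile of random lists. Of the 15 antigen presentation genes *GCH1* rose (1.14) and *HLA-DPA1* fell by 0.44 (camera adjusted p = 0.809). In the type I list *HERC6* fell by 0.40 (camera adjusted p = 0.509), in the JAK-STAT list *SOCS3* rose and *STAT6* fell by 0.36 (camera adjusted p = 0.737), in the ribosome biogenesis list *RRP1B* fell by 0.39 (camera adjusted p = 0.960), and in the mitotic and S-phase list *MCM5* fell by 0.31 (camera adjusted p = 0.714).

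Markers of other cell types were mostly at the floor. Of the leukocyte markers on the array 0 of 14 were above the floor in 2 arrays, of the endothelial markers 1 of 10 with a highest level of 90.7, of the melanocyte and Schwann markers 1 of 7 with a highest level of 174, and of the keratinocyte markers 3 of 12 with a highest level of 1852. With CHX the keratinocyte markers had 0 calls over all genes and 2 that were lower adjusted over the list alone, *KRT10* (-0.27) and *SFN* (-0.25).

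The unstimulated CHX-free uninfected array stood apart in several of its controls. Its *ACTB* 3' to 5' ratio was 13.9 against 6.94 to 10.2 on the other arrays and its *GAPDH* ratio 2.27 against 1.58 to 2.01. Its BioB control was at 356 against 635 to 829.6, and its BioC control at 455 against 1092 to 1435. A second probe set for each was inside the range of the other arrays, BioB at 871 against 713 to 951 and BioC at 1681 against 1639 to 2124. Without it the counts were 19 genes for IFN-γ, 15 of them shared, 1 for infection and 987 for CHX, 735 of them shared. Across genes, the IFN-γ differences of different backgrounds had correlations of -0.05 to 0.40, the infection differences 0.02 to 0.23 and the CHX differences 0.57 to 0.64.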
